A study of Mus musculus with 18 samples.

How the data were processed

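The count table, as deposited, holds raw counts for 24537 gene symbols in the 18 libraries, and no normalization was applied to it. Per the labels, the submitters' processing named STAR, HOMER and DESeq2 and the mouse builds GRCm38 and mm10, with no versions and no role for each tool. How reads were trimmed, aligned, assigned to genes and filtered, and whether the library preparation kept the strand, is not given in the sources used here. The table is made of whole numbers. Of its symbols, 23675 matched the GRCm38 reference annotation used for coordinates and gene types, and 2231 had no count in any library. Libraries held from 4113713 to 5945518 counts and from 14936 to 17518 genes with a count. The ribosomal transcript Rn45s took 0.996 to 1.68% of counts and Lars2 0.274 to 0.375%. Squared differences between libraries of a group, scaled by counting error, averaged from 2.44 to 8.55, where 1 library sequenced again would give values near 1 and a copy 0.

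Before the data were examined, the groups, contrasts, tests, gene lists, other settings to try and the rule for naming genes were written down. All 18 libraries entered one model with a mean for each of 6 groups (genotype by LCA dose). In edgeR 4.0.16 (R 4.3.3), genes were filtered by group with filterByExpr, leaving 11651, libraries were scaled by TMM, and dispersions and a robust quasi-likelihood fit gave F tests. The common dispersion was 0.00968, a biological coefficient of variation of 0.0984. The median standard error of a log2 fold change in WT LCA50 against WT control was 0.155. There were 12 contrasts: LCA50 and LCA10 against control in each genotype, KO against WT at each dose, the difference between genotypes in each response, and, averaged over genotypes, each dose against control and LCA50 against LCA10. P-values were adjusted by Benjamini-Hochberg within a contrast, and genes under 0.05 were called. Standard errors were the absolute log2 fold change over the square root of F. CPM are edgeR's cpm values on TMM-scaled library sizes, and principal components were taken from log2 CPM with a prior count of 2. The labels name no batch, so the fit holds no covariate and no block.

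Gene lists numbered 28, of which 6 hold markers of CD8 T, CD4 T, B, NK and gamma delta T, myeloid, and red cells and platelets. The others cover ATF4 targets, endoplasmic reticulum chaperones, heat shock, NRF2 targets, bile acid receptors and transport, cholesterol synthesis, fatty acid synthesis, liver X receptor targets, T cell receptor induced genes, effector genes, inhibitory receptors, naive and memory genes, STAT5 targets, the interferon response, hypoxia, glycolysis, the respiratory chain, p53 targets, apoptosis, DNA replication, mitosis, and lysosome and autophagy. Members were tested as single genes, adjusted over all genes and over the list alone. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, with an estimated correlation as an alternative. Named genes followed a rule. Nr4a1 came first in every contrast. Called genes with a mean CPM of at least 5, no overlap between the libraries compared (single-dose, single-genotype contrasts), and a symbol that is not a predicted gene were ranked by log2 fold change. The 10 highest and 10 lowest were named for the LCA50 contrasts within genotype and for KO control against WT control, and 5 and 5 for the others. Of each list, up to 3 called members with the smallest p each way were named, or the 2 most abundant where none was called. Where under 10 genes were called, the 5 smallest p-values were given as values. This made 275 genes.

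Settings written down beforehand were DESeq2 1.42.0 (Wald test), DESeq2 size factors inside edgeR, no filter, a filter of mean CPM of at least 5, a fit of the compared groups alone, the replicate number as a block, each library left out in turn, a test against a log2 fold change of 0.5 with glmTreat, and for lists an estimated correlation, fry, and the block. Chosen after seeing the data were a covariate of library background, the LCA50 library with the highest background in each genotype left out, Rn45s and Lars2 left out, limma-voom with sample quality weights, and the lists with libraries left out. Counting the calls shared by the genotypes under settings other than the main one was also decided then. Background was the summed count of receptor genes of the olfactory, vomeronasal and trace amine families under the filter, per total count of the library. Groupings of libraries were compared with other splits, all 10 for 3 against 3 libraries and 100 drawn for averaged contrasts, response differences and medians of lists. The code was checked on simulated data in which 200 seeded genes were changed in WT LCA50. Of 50 genes at each size, it recovered 35 at 1.5-fold, 43 at 2-fold, 46 at 3-fold and 45 at 4-fold, and DESeq2 recovered 34, 44, 45 and 44. Of 182 genes called there, 13 (7.14%) had not been changed. In the unchanged WT LCA10 contrast 0 were called, as were 0 of 20 random lists. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.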

Results

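The series measured gene counts by RNA sequencing in mouse CD8+ T cells treated with lithocholic acid (LCA), a secondary bile acid made by gut bacteria. The question was how LCA acts on T cells that have or lack Nur77, the nuclear receptor encoded by Nr4a1. Cells labelled WT had received a scrambled guide RNA and cells labelled KO a guide kit against Nr4a1, before activation through CD3 and CD28. Each genotype was then kept overnight without LCA (control) or with 10 or 50 µM LCA, called LCA10 and LCA50 here. The 6 groups held 3 libraries each, 18 in all. Total counts per library ran from 4113713 to 5945518. The group means (± SD) were 4963815 ± 72783 for WT control, 5105739 ± 101915 for WT LCA10 and 4642267 ± 290728 for WT LCA50. In KO they were 5449176 ± 448221 for control, 4869622 ± 408145 for LCA10 and 4799537 ± 593946 for LCA50. Of 24537 listed genes, 11651 had enough counts to be tested. Changes are log2 fold changes ± standard error from edgeR's quasi-likelihood test, with 3 libraries in each group and Benjamini-Hochberg adjustment. A gene is called, or said to have risen or fallen, below an adjusted p of 0.05. The labels do not say whether replicates were separate animals or cultures, so the p-values measure the spread between these libraries, which may be technical. Library numbers ran in the order of the groups, so a trend along that order could not be separated from treatment.

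Nr4a1 (chromosome 15, 101253902 to 101274795, GRCm38) had similar counts in every group. Its counts in replicates 1, 2 and 3 were 55, 58, 29 in WT control, 43, 82, 43 in WT LCA10 and 84, 74, 35 in WT LCA50. They were 61, 41, 71 in KO control, 48, 47, 48 in KO LCA10 and 66, 38, 36 in KO LCA50. Mean CPM (counts scaled to library size, ± SD) were 9.6 ± 3.24, 11.1 ± 4.73 and 13.6 ± 5.18 in WT and 10.6 ± 2.48, 9.91 ± 0.823 and 10.1 ± 4.87 in KO, in the same order. The KO against WT change was 0.14 ± 0.33 in control cells (edgeR adjusted p = 0.963), -0.16 ± 0.33 at LCA10 and -0.45 ± 0.33 at LCA50, none of them called. Nor was it called with LCA, at 0.51 ± 0.33 in WT LCA50 and -0.09 ± 0.33 in KO LCA50. A guide that leaves small insertions or deletions need not lower the transcript. Gene counts do not show the edited sequence, so they neither back the KO label nor speak against it. Across all genes, the second principal component separated the genotypes, with group means of 13.7, 9.42 and 14.1 in WT and -10.6, -11.8 and -14.8 in KO for control, LCA10 and LCA50. The first component held 18.9% of the variance against 11.4%, with means of -15.9, -6.35 and 21.5 in WT and -11.1, -4.35 and 16.2 in KO. KO LCA50 replicate 1 stood at 41.9, and replicates 2 and 3 at 0.693 and 5.82. Within WT control, WT LCA50 and KO LCA50, but not within the other groups, this component ordered libraries by receptor background.

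In WT cells, LCA50 raised genes of amino acid supply and stress and lowered genes of lipid metabolism and of the naive state. Cth, which makes cysteine, rose most among the named genes (3.08 ± 0.69, edgeR adjusted p = 0.0154), from 3.72 ± 1.16 to 31.6 ± 11.3 CPM (chromosome 3, 157894248 to 157925081, GRCm38). The stress gene Nupr1 (2.55 ± 0.39), the nuclear lamina gene Lmna (2.43 ± 0.25), the retinoid receptor Rxra (1.77 ± 0.30) and the glycine transporter Slc6a9 (1.97 ± 0.43) rose. So did the ATF4 feedback gene Trib3 (1.65 ± 0.39) and the arginine transporter Slc7a3 (1.63 ± 0.31). The adhesion kinase Ptk2 (2.11 ± 0.47) and the actin regulator Enah (1.63 ± 0.39) rose with them. At the other end, the neutrophil granule gene Ngp fell by 4.43 ± 0.94, from 9.61 ± 5.8 to 0.402 ± 0.696 CPM, though DESeq2 did not call it (-4.56, adjusted p = 0.0935). The desaturase Scd1 fell by 3.31 ± 0.53 (chromosome 19, 44394450 to 44407709) and the sterol exporter Abcg1 by 2.48 ± 0.32 (chromosome 17, 31057694 to 31117984). The repressor Hic1 fell by 2.58 ± 0.35 and the ADP-ribosyltransferase Art2b by 2.45 ± 0.41. The phosphatase Acp5 (-2.07 ± 0.17) and the memory marker Ly6c2 (-1.95 ± 0.38) fell as well. Art2b and Ly6c2 have close paralogs, so reads may be split between copies. In all, 1000 genes were called, 426 higher and 574 lower, of which 69 and 77 changed by at least 2-fold.

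Grouped by fixed lists, the targets of ATF4 in the integrated stress response rose in WT LCA50. There 28 of 43 tested members rose and 0 fell (33 and 1 adjusted over the list alone), with a median of 0.53 (camera adjusted p = 2.83e-36, adjusted p = 0.033 with an estimated correlation). Examples were asparagine synthetase Asns (0.89 ± 0.09) and both chains of an amino acid exchanger, Slc7a5 (0.76 ± 0.07) and Slc3a2 (0.73 ± 0.07). The chaperone genes of the endoplasmic reticulum did not move with them: 2 of 36 tested members rose and 2 fell (2 and 5 adjusted over the list alone), with Herpud1 up (0.49 ± 0.09) and Selenok down (-0.60 ± 0.10). Of the cholesterol synthesis genes, 0 rose and 11 of 24 fell (17 adjusted over the list alone), with a median of -0.51 (camera adjusted p = 4e-12, adjusted p = 0.15 with an estimated correlation). Msmo1 (-0.70 ± 0.11), Acat2 (-0.65 ± 0.12) and the lipid carrier Stard4 (-0.63 ± 0.12) were among those that fell. Fatty acid synthesis genes fell in 6 of 16 cases (8 adjusted over the list alone; camera adjusted p = 0.00085, adjusted p = 0.195 with an estimated correlation). Acly, which makes cytosolic acetyl-CoA, was one (-0.33 ± 0.09). Liver X receptor targets fell in 5 of 10 (5 adjusted over the list alone; camera adjusted p = 1.85e-05, adjusted p = 0.033 with an estimated correlation). They included Smpdl3a (-1.22 ± 0.25) and the lipogenic regulator Srebf1 (-0.38 ± 0.09). Antioxidant targets of NRF2 went both ways, 8 up and 3 down of 24 (10 and 3 adjusted over the list alone; camera adjusted p = 0.00736, adjusted p = 0.109 with an estimated correlation). The glutathione gene Gclm (0.76 ± 0.11) and the ferritin chains Ftl1 (0.57 ± 0.09) and Fth1 (0.31 ± 0.06) rose, while Txn1 (-0.29 ± 0.08) fell.

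Genes of the naive and memory state fell in WT LCA50: 1 of 23 tested members rose and 13 fell (1 and 13 adjusted over the list alone), median -0.32 (camera adjusted p = 1.51e-08, adjusted p = 0.00147 with an estimated correlation). The cytokine receptor Il7r (-0.70 ± 0.12) and Dapl1 (-1.44 ± 0.19) fell, whereas the survival gene Bcl2 rose (0.49 ± 0.08). Effector genes split, 3 up and 4 down of 27 (4 and 6 adjusted over the list alone; camera adjusted p = 0.437). The lymphotoxin Lta (1.12 ± 0.13), Eomes (0.65 ± 0.10) and Tnf (0.53 ± 0.15) rose and Tbx21 (-0.72 ± 0.15) and the granule proteoglycan Srgn (-0.51 ± 0.10) fell. Inhibitory receptors split too, 3 up and 5 down of 18, the same counts adjusted over the list alone (camera adjusted p = 0.328). Havcr2 (0.83 ± 0.21) and the exhaustion factor Tox (0.97 ± 0.29) rose and the receptors Btla (-0.98 ± 0.19) and Ctla4 (-0.65 ± 0.09) fell. T cell receptor induced genes rose in 6 of 28 and fell in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 0.000168, adjusted p = 0.111 with an estimated correlation). The transcription factor Fosl2 rose (1.05 ± 0.18) and the receptor brake Cd5 fell (-0.65 ± 0.12). Targets of STAT5 rose in 6 of 20 and fell in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 0.000316, adjusted p = 0.0853 with an estimated correlation). The ligand-activated factor Ahr (1.25 ± 0.27) and the cytokine signalling brake Cish (0.61 ± 0.13) rose. Mitotic genes fell in 9 of 30 (12 adjusted over the list alone; median -0.18; camera adjusted p = 2.72e-08, adjusted p = 0.15 with an estimated correlation), such as the spindle gene Nusap1 (-0.45 ± 0.07). Glycolysis genes fell in 7 of 21 (8 down and 1 up adjusted over the list alone; camera adjusted p = 0.00184, adjusted p = 0.0719 with an estimated correlation), such as Pdk1 (-0.47 ± 0.08).

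The number of calls in WT LCA50 depended on the libraries. Counts from 1470 olfactory, pheromone and trace amine receptor genes that T cells should not express made up 121, 139 and 223 CPM in the WT LCA50 replicates, against a mean of 79.3 in WT control. With that background as a covariate, which is partly confounded with LCA50 in WT, 339 genes were called. Of these, 17 were ATF4 targets that rose and 1 was a cholesterol synthesis gene that fell. Cth (2.03 ± 0.57, edgeR adjusted p = 0.0823), Trib3 (1.00 ± 0.36, adjusted p = 0.197), Tnf (0.24 ± 0.17) and Tbx21 (-0.40 ± 0.13) lost their calls there. Of the other genes named above, so did Ptk2 (1.21 ± 0.50), Slc6a9 (1.24 ± 0.36), Enah (0.87 ± 0.40), Ly6c2 (-1.42 ± 0.42), Acat2 (-0.47 ± 0.14), Stard4 (-0.50 ± 0.15), Srebf1 (-0.18 ± 0.10), Acly (-0.18 ± 0.10), Txn1 (-0.17 ± 0.09), Cd5 (-0.41 ± 0.14) and Cish (0.43 ± 0.14), all with smaller changes than before. Havcr2 (0.83 ± 0.26) and Tox (1.01 ± 0.37) also lost theirs, with changes no smaller than before but larger standard errors. Cth also lost its call without WT control replicate 1 (2.96, adjusted p = 0.0632), WT control replicate 2 or WT LCA50 replicate 2. In KO LCA50 the same covariate did not lower the count, with 998 genes called against 740 without it, 738 of them in both.

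**Figure D1:**
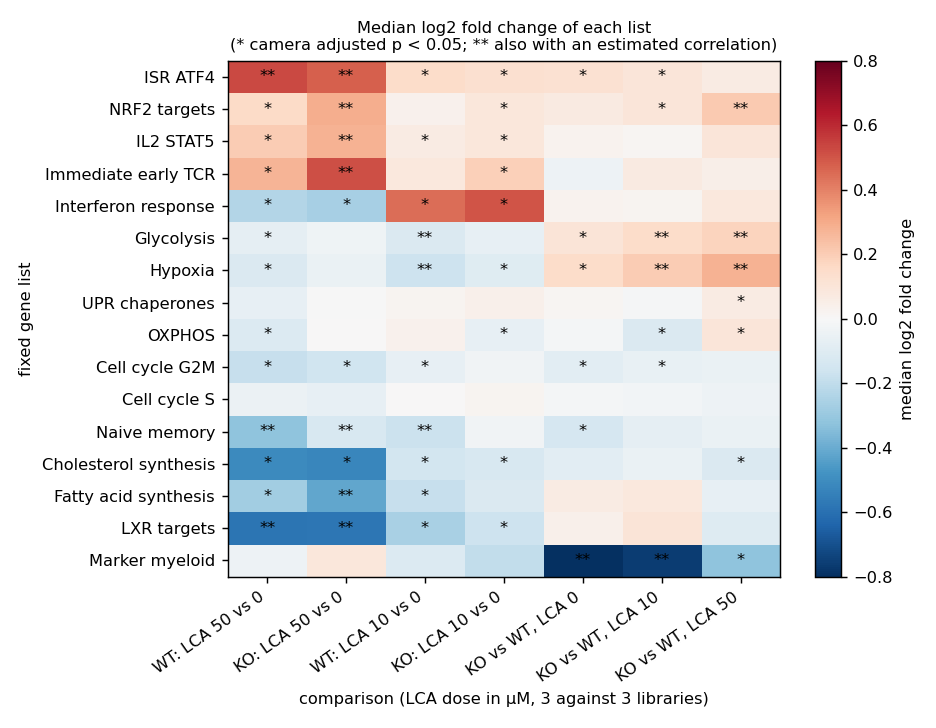
Median log2 fold change of the members of 16 gene lists (vertical axis) in each comparison of 3 against 3 libraries (horizontal axis), as colour, with marks for lists that camera called. The ATF4 list stands at 0.53 and 0.48 in the LCA50 comparisons and the interferon list at 0.45 and 0.50 at LCA10.

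In KO cells, LCA50 moved the ATF4, lipid and naive state lists in the directions seen in WT. Cth (3.07 ± 0.61), Lmna (2.24 ± 0.23), Rxra (1.89 ± 0.29), Trib3 (1.76 ± 0.38) and Nupr1 (1.62 ± 0.33) rose, and Scd1 (-2.92 ± 0.44), Hic1 (-2.82 ± 0.38), Abcg1 (-2.54 ± 0.31), Art2b (-1.94 ± 0.39) and Tspan2 (-1.76 ± 0.35) fell. The cytokine Ifng (3.01 ± 0.74), the actin-severing gene Scin (3.28 ± 0.79), the lipoprotein receptor Vldlr (1.85 ± 0.50) and the trafficking gene Agap1 (3.12 ± 0.87) rose. The matrix gene Itih5 (-2.85 ± 0.37), the fucosyltransferase Fut4 (-1.87 ± 0.34) and the lipid transfer gene Pltp (-1.68 ± 0.27) fell. edgeR called 740 genes, 341 higher and 399 lower, with 66 and 75 at 2-fold or more. Of the ATF4 targets, 28 of 43 rose and 0 fell (36 and 0 adjusted over the list alone), median 0.48 (camera adjusted p = 3.18e-28, adjusted p = 0.0366 with an estimated correlation). Asns stood at 0.62 ± 0.09 and Slc3a2 at 0.58 ± 0.07. Cholesterol synthesis genes fell in 10 of 24 (21 adjusted over the list alone), median -0.52 (camera adjusted p = 2.74e-16, adjusted p = 0.0875 with an estimated correlation). The squalene enzyme Sqle (-0.56 ± 0.11) and Acat2 (-0.60 ± 0.12) were among them. Fatty acid synthesis genes fell in 6 of 16 (9 adjusted over the list alone; camera adjusted p = 3.67e-08, adjusted p = 0.0366 with an estimated correlation), with the acetyl-CoA gene Acss2 at -1.18 ± 0.22. Liver X receptor targets fell in 4 of 10 (5 adjusted over the list alone; camera adjusted p = 6.18e-08, adjusted p = 0.0108 with an estimated correlation). NRF2 targets rose in 8 of 24 and fell in 0 (11 and 2 adjusted over the list alone; camera adjusted p = 3e-07, adjusted p = 0.0108 with an estimated correlation), with Gclm at 0.95 ± 0.11.

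The T cell lists also moved in KO LCA50. Naive and memory genes fell in 11 of 23 and rose in 1 (11 and 2 adjusted over the list alone; camera adjusted p = 0.00052, adjusted p = 0.0188 with an estimated correlation). Il7r (-0.50 ± 0.11) and the transcription factor Tcf7 (-0.46 ± 0.10) fell. Of the effector genes, 5 of 27 rose and 1 fell (6 and 2 adjusted over the list alone), with a median of 0.00, a mean of 0.23 and a test direction up (camera adjusted p = 0.183). Lta (1.42 ± 0.13), Tnf (0.93 ± 0.15) and Eomes (0.52 ± 0.10) rose and Tbx21 (-0.59 ± 0.15) fell. Inhibitory receptors again split, 3 up and 2 down of 18, as adjusted over the list alone, with Havcr2 (1.28 ± 0.21) up and Btla (-1.17 ± 0.18) down. Their median was -0.04, their mean 0.04 and the test direction down, without a call. T cell receptor induced genes rose in 8 of 28 and fell in 1 (12 and 2 adjusted over the list alone; camera adjusted p = 4.76e-07, adjusted p = 0.0366 with an estimated correlation), with the phosphatase Dusp2 at 0.91 ± 0.11. STAT5 targets rose in 8 of 20 (11 adjusted over the list alone; camera adjusted p = 3.16e-07, adjusted p = 0.0201 with an estimated correlation), with the cytokine Osm at 0.78 ± 0.14. Mitotic genes fell in 7 of 30 (11 adjusted over the list alone; camera adjusted p = 6.18e-08, adjusted p = 0.177 with an estimated correlation). KO LCA50 replicate 1 stood apart, with Cth at 124 CPM against 23.4 and 24.7 in replicates 2 and 3. Its receptor gene background was 164 CPM against 47.2 and 93.4. Without it 435 genes were called, and without it and WT LCA50 replicate 3 together 428. Among those were 19 ATF4 targets up and 6 cholesterol synthesis genes down. Ifng (2.31 ± 0.66, edgeR adjusted p = 0.0549), Agap1 (0.61 ± 0.66, adjusted p = 0.736) and Vldlr (0.99 ± 0.38, adjusted p = 0.178) lost their calls, so replicate 1 carried most of the change of Agap1. A fit of the compared groups alone called 372 genes, and there Cth (3.06, adjusted p = 0.224), Trib3 (adjusted p = 0.248), Ifng (0.147), Scin, Vldlr, Agap1, Fut4, Sqle and Tbx21 lost their calls at almost the same changes but with larger standard errors.

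Whether the response to LCA differs between cells labelled KO and WT was tested as the difference between the genotypes' responses. Since gene counts do not show the loss of Nur77, this test alone cannot show whether the response needs it. At LCA50, 429 genes were called in both genotypes in the same direction (175 higher and 254 lower), where independent lists would share 32.1, and 0 were called in opposite directions. These comparisons share no library. Of the genes called in WT, 940 (94.0%) had the same sign in KO, and of those called in KO 721 (97.4%) had it in WT. The median ratio of changes was 0.667 in KO for the WT calls and 0.821 in WT for the KO calls. Choosing genes by their call in 1 genotype lowers such a ratio, so neither shows a weaker response. Across all tested genes the responses correlated at r = 0.434, where genes are not independent replicates. The direct test of the difference called 0 genes with edgeR and 1 with DESeq2. There were 729 genes at an unadjusted p under 0.05 where 583 would be expected by chance. The smallest p belonged to Thbs1, a matrix glycoprotein gene (2.60 ± 0.48, edgeR adjusted p = 0.172). Thbs1 went from 16.8 ± 1.37 to 7.93 ± 2.62 CPM in WT and from 8.83 ± 1.45 to 25.9 ± 17.2 in KO. camera called 6 of 26 lists for the LCA50 difference at its preset correlation and 0 with an estimated correlation. At LCA10 edgeR called 0 genes, with 382 at an unadjusted p under 0.05, and DESeq2 0. The 382 lie below the same 583, so 583 is not a firm level for chance here. The 729 at LCA50 are thus not evidence of genes that respond differently. At LCA10 the platelet integrin Itga2b (3.63 ± 0.84) and Slc7a6 (-0.62 ± 0.17) were among the smallest p-values. An uncalled difference does not show equal responses. At LCA50 leaving out KO LCA50 replicate 1 gave 6 calls.

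**Figure D2:**
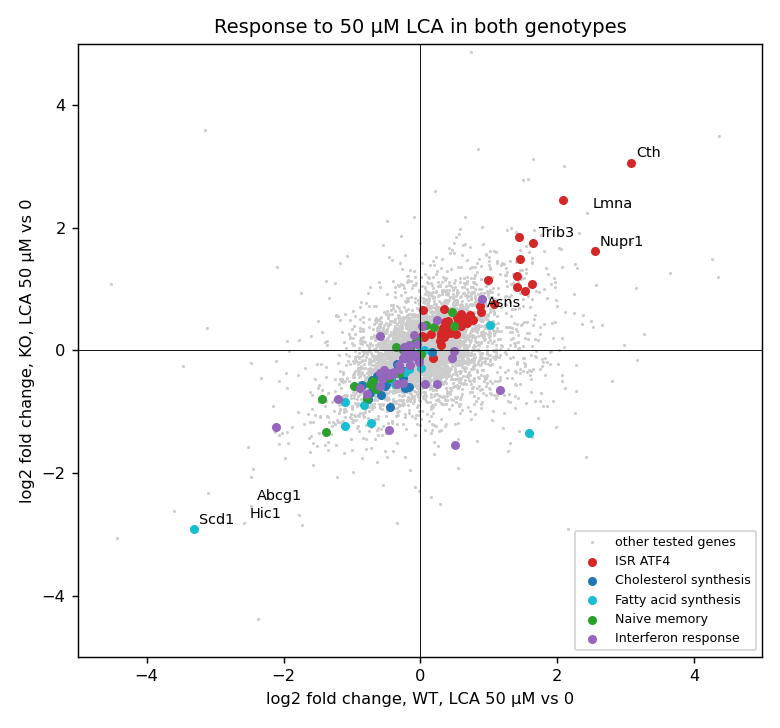
Log2 fold change of each tested gene with LCA50 in WT (horizontal axis) against KO (vertical axis), with members of chosen lists in colour. ATF4 targets lie towards the upper right and cholesterol and fatty acid synthesis genes mostly towards the lower left, and no gene was called in opposite directions.

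The lower dose raised interferon-stimulated genes in both genotypes. In WT LCA10 the antiviral genes Mx2 (2.20 ± 0.46), Oasl1 (1.77 ± 0.31) and Rtp4 (1.00 ± 0.16), the chemokine Cxcl10 (1.89 ± 0.38) and the DNA sensor Ifi204 (1.63 ± 0.32) rose, with Lmna (1.58 ± 0.26), Lta (0.70 ± 0.13) and Eomes (0.51 ± 0.10). In KO LCA10 Ifi204 (1.85 ± 0.30), Isg15 (1.52 ± 0.25), Oasl1 (1.32 ± 0.30), Rtp4 (1.20 ± 0.17), Lmna (1.53 ± 0.23) and Lta (0.80 ± 0.13) rose. Hic1 (-2.08 ± 0.33 in WT and -2.63 ± 0.37 in KO), Abcg1 (-1.26 ± 0.28 and -1.66 ± 0.29), the purine receptor P2rx4 (-1.32 ± 0.30 and -1.35 ± 0.30) and Tg (-1.33 ± 0.19 and -0.80 ± 0.18) fell in both. The annotation lists Mx2 as a transcribed pseudogene, and it may share reads with Mx1. edgeR called 45 genes in WT (25 higher, 20 lower) and 38 in KO (24 higher, 14 lower). Of these, 22 were called in both in the same direction where independent lists would share 0.0755. Across genotypes and doses, which share no library, 31 of the WT LCA10 calls were called the same way in KO LCA50 (1.42 for independent lists). Likewise 25 of the KO LCA10 calls were called the same way in WT LCA50 and 1 the opposite way (1.57). Of the 40 interferon-stimulated genes, 6 rose in WT (23 adjusted over the list alone; median 0.45; camera adjusted p = 2.15e-24, adjusted p = 0.0565 with an estimated correlation). In KO 5 rose (21 adjusted over the list alone; median 0.50; camera adjusted p = 3.28e-23, adjusted p = 0.169 with an estimated correlation). Without WT LCA10 replicate 2 the calls among all genes in WT LCA10 went from 45 to 4, all of them lower, so no interferon-stimulated gene was called higher, with Oasl1 (1.69, edgeR adjusted p = 0.0533) no longer called. In a fit of the compared groups alone Cxcl10 in WT LCA10 lost its call (1.88, adjusted p = 0.279). Without KO LCA10 replicate 2 the calls among all genes in KO LCA10 went from 38 to 6 (5 higher, 1 lower).

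Averaged over the genotypes, with 6 libraries against 6, LCA10 called 212 genes (118 higher, 94 lower). Of the interferon-stimulated genes 22 of 40 rose and 0 fell (28 and 1 adjusted over the list alone), with a median of 0.46 (camera adjusted p = 4.04e-35, adjusted p = 0.0302 with an estimated correlation). Oasl1 (1.54 ± 0.21), Cxcl10 (1.52 ± 0.26), Rtp4 (1.10 ± 0.12) and Xaf1 (0.72 ± 0.09) rose. In a division of the list chosen after its values were seen, the guanylate-binding proteins, immunity-related GTPases and Irf1 stayed out of the rise. None of these 8 members was called higher, with a median of -0.04, against 22 of the 32 other members, with a median of 0.64. The chemokine Ccl5 (0.96 ± 0.18), the exchanger chains Slc7a5 (0.28 ± 0.05) and Slc3a2 (0.29 ± 0.05), Gclm (0.35 ± 0.08) and Ftl1 (0.34 ± 0.07) rose too. The trafficking genes Klf2 (-0.57 ± 0.11) and S1pr1 (-0.46 ± 0.11), Btla (-0.64 ± 0.13) and Scd1 (-1.26 ± 0.28) fell. ATF4 targets rose in 3 of 43 (11 adjusted over the list alone; camera adjusted p = 1.4e-07, adjusted p = 0.283 with an estimated correlation). Hypoxia genes fell in 3 of 22 (7 down and 1 up adjusted over the list alone; camera adjusted p = 4.04e-07, adjusted p = 0.0302 with an estimated correlation) and glycolysis genes in 2 of 21 (7 down and 1 up adjusted over the list alone; camera adjusted p = 4.97e-05, adjusted p = 0.0302 with an estimated correlation). Naive genes fell in 2 of 23 (7 down and 1 up adjusted over the list alone; camera adjusted p = 0.00275, adjusted p = 0.0302 with an estimated correlation). DESeq2 did not call Scd1 (-1.26, adjusted p = 0.115).

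At LCA50 the interferon-stimulated genes stood below control in both genotypes. In WT 9 of 40 fell and 0 rose (11 and 0 adjusted over the list alone; median -0.23; camera adjusted p = 1.49e-05, adjusted p = 0.309 with an estimated correlation). In KO 8 fell and 0 rose (14 and 1 adjusted over the list alone; median -0.26; camera adjusted p = 9.8e-06, adjusted p = 0.444 with an estimated correlation). Those that fell included Irf1 (-0.43 ± 0.07 in WT and -0.38 ± 0.07 in KO), Igtp (-0.40 ± 0.07 and -0.38 ± 0.07) and Iigp1 (-0.59 ± 0.08 and -0.37 ± 0.08). Averaged over genotypes, the median was -0.40 for that GTPase group against -0.14 for the other members. Set against LCA10 directly, LCA50 lowered 36 of the 40 (39 adjusted over the list alone; median -0.89; camera adjusted p = 1.31e-65, adjusted p = 0.00795 with an estimated correlation). Mx2 (-2.15 ± 0.32), Ifit1bl1 (-1.72 ± 0.25), Mx1 (-1.68 ± 0.32) and Rsad2 (-1.64 ± 0.41) fell most among the named genes. The dose comparison called 667 genes, 263 higher and 404 lower. ATF4 targets rose in 32 of 43 (37 adjusted over the list alone; camera adjusted p = 3.74e-40, adjusted p = 0.0255 with an estimated correlation), with Cth at 2.26 ± 0.43, Vldlr at 1.61 ± 0.38 and Nupr1 at 1.23 ± 0.23. Cholesterol synthesis genes fell in 9 of 24 (20 adjusted over the list alone; camera adjusted p = 2.07e-16, adjusted p = 0.101 with an estimated correlation), with Insig1 at -0.72 ± 0.14. Dapl1 (-0.82 ± 0.15) fell from LCA10 to LCA50, and Havcr2 (0.82 ± 0.15), Ahr (0.93 ± 0.19) and Lta (0.52 ± 0.09) rose. With the receptor background as a covariate 283 genes were called in this dose comparison, 28 of them interferon-stimulated genes that fell. There Vldlr (0.91 ± 0.33, adjusted p = 0.183) and Nupr1 (0.72 ± 0.22, adjusted p = 0.0774) lost their calls with smaller changes. Rsad2 (-1.41 ± 0.51, adjusted p = 0.234) and Mx1 (-1.57 ± 0.40, adjusted p = 0.0733) lost theirs with changes nearly as large as before and larger standard errors. In a fit of the compared groups alone Rsad2 (0.112), Vldlr (0.0832) and Cth (0.0512) lost theirs at almost the same changes.

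**Figure D3:**
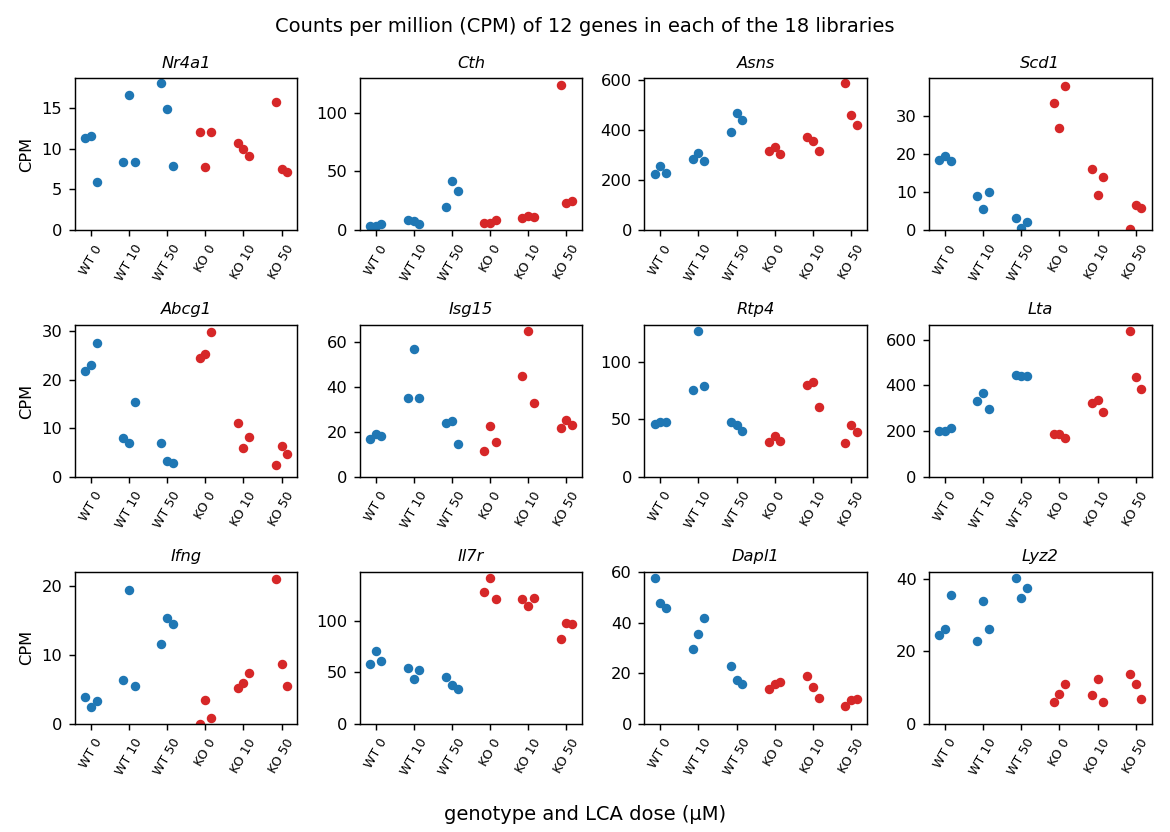
CPM of 12 genes (vertical axes) in each library (points), by genotype and LCA dose in µM (horizontal axis). Isg15 and Rtp4 are highest at 10 µM in both genotypes, Cth and Lta at 50 µM, and Lyz2 is lower in KO than in WT at every dose.

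Averaged over genotypes, LCA50 against control called 1925 genes, 916 higher and 1009 lower. ATF4 targets rose in 35 of 43 (37 up and 1 down adjusted over the list alone; camera adjusted p = 5.04e-40, adjusted p = 0.0195 with an estimated correlation). Cholesterol synthesis genes fell in 18 of 24 (23 adjusted over the list alone; camera adjusted p = 2.74e-17, adjusted p = 0.0745 with an estimated correlation). Mitotic genes fell in 16 of 30 (20 adjusted over the list alone; camera adjusted p = 1.04e-09, adjusted p = 0.0926 with an estimated correlation). Ifng rose (2.56 ± 0.49), as did the exporter Abcc1 (0.33 ± 0.08), while the exporter Abcb1b fell (-0.46 ± 0.09). Both exporters are on the list of bile acid receptors and transport, where 2 of 11 tested members rose and 1 fell (2 and 1 adjusted over the list alone) of 28 listed (camera adjusted p = 0.515). Heat shock genes rose in 3 of 16 (3 adjusted over the list alone; camera adjusted p = 0.112), with Hsph1 at 0.28 ± 0.06. Lysosome and autophagy genes fell in 10 of 39 and rose in 3 (11 and 3 adjusted over the list alone; camera adjusted p = 0.0333, adjusted p = 0.0745 with an estimated correlation), with the cathepsin Ctsa at -0.38 ± 0.06. Of the DNA replication genes 2 of 33 tested members rose and 5 fell (2 and 5 adjusted over the list alone) (camera adjusted p = 0.172). Among respiratory chain genes 2 of 63 tested members rose and 5 fell (1 and 5 adjusted over the list alone) (camera adjusted p = 0.112). For p53 targets 3 of 27 tested members rose and 5 fell (3 and 6 adjusted over the list alone), and for apoptosis regulators 5 of 28 tested members rose and 6 fell (5 and 6 adjusted over the list alone), with camera adjusted p of 0.124 and 0.652. Of the CD8 identity genes 0 of 13 tested members rose and 3 fell (1 and 3 adjusted over the list alone) (camera adjusted p = 0.0123, adjusted p = 0.416 with an estimated correlation), with the co-receptor chain Cd8b1 at -0.47 ± 0.05 and Cd3g at -0.25 ± 0.07. Of the CD4 T cell markers 4 of 5 tested members rose and 0 fell (5 and 0 adjusted over the list alone) (camera adjusted p = 5.83e-05, adjusted p = 0.023 with an estimated correlation). Cd4 itself was not among those tested, with at most 6 counts in any library and a mean of 0.312 CPM. The zinc finger factor Ikzf4 (1.26 ± 0.15), the follicle homing receptor Cxcr5 (1.30 ± 0.34) and the cytokine Il9 rose, genes that activated CD8 T cells can express as well. Il9 had no count in WT control and 0.478 ± 0.504 CPM in WT LCA50, and went from 0.367 ± 0.186 to 4.42 ± 2.02 in KO. B cell markers split, with Fcmr (1.08 ± 0.29) up and Cd79b (-0.84 ± 0.21) down of 6 tested (2 up and 1 down adjusted over the list alone; camera adjusted p = 0.855).

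Without LCA, KO cells differed from WT cells in 73 genes (38 higher, 35 lower). Il7r was higher in KO (1.06 ± 0.11, edgeR adjusted p = 1.72e-07), at 131 ± 10.6 against 62.8 ± 6.65 CPM. The uridine phosphorylase Upp1 (1.31 ± 0.13), the cytokine Il24 (1.70 ± 0.24), the kinase Alpk2 (1.71 ± 0.31), and the ectoenzyme Bst1 (1.57 ± 0.34) were higher as well. So were the class I gene H2-Q10 (1.48 ± 0.28) and the receptors Gpr141 (1.17 ± 0.22) and Tnfrsf8 (1.17 ± 0.28). H2-Q10 shares sequence with other class I genes, so its counts are uncertain. Lower in KO were Dapl1 (-1.71 ± 0.19), the inhibitory lectin Klrc1 (-1.17 ± 0.14), the tetraspanin Tspan32 (-1.78 ± 0.31), and the signalling brake Spry1 (-1.32 ± 0.25). The steroid enzyme Hsd11b1 (-1.23 ± 0.19), Klf2 (-0.70 ± 0.15), Dusp2 (-0.48 ± 0.11) and the co-receptor Cd8a (-0.25 ± 0.06) were lower too. ATF4 targets were higher in 2 of 43 (6 adjusted over the list alone; camera adjusted p = 2.36e-07, adjusted p = 0.523 with an estimated correlation), namely Asns (0.44 ± 0.09) and Stc2 (0.65 ± 0.16). Hypoxia targets were higher in 2 of 22 (3 adjusted over the list alone; camera adjusted p = 4.46e-05, adjusted p = 0.128 with an estimated correlation), namely Bhlhe40 (0.33 ± 0.08) and the prolyl hydroxylase P4ha2 (0.96 ± 0.21). Without KO control replicate 2 28 genes were called and without WT control replicate 2 53, the lowest and highest counts with 1 library left out.

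With LCA the genotypes differed in 77 genes at LCA10 (48 higher in KO, 29 lower) and 226 at LCA50 (165 higher, 61 lower). Of the calls in control cells, 38 were also called the same way at LCA10 and 37 at LCA50, where independent lists would share 0.244 and 0.721. The guides were given before LCA, and the labels do not say whether the libraries of a genotype came from separate edits. A difference between pools of cells would also recur at each dose, so the overlap cannot tell it from an effect of the guide. Il7r (1.26 ± 0.11 at LCA10 and 1.26 ± 0.12 at LCA50) and Il24 (1.71 ± 0.24 and 2.04 ± 0.21) were higher and Dapl1 (-1.31 ± 0.19 and -1.08 ± 0.22) and Spry1 (-1.10 ± 0.24 and -1.27 ± 0.23) lower at both doses. At LCA10 the surface gene Ly6c1 (2.31 ± 0.40) and the inflammasome gene Nlrp6 (1.55 ± 0.32) were higher, and glycogen phosphorylase Pygm (-1.38 ± 0.27) lower. At LCA50 the cytokines Csf2 (2.37 ± 0.54) and Il9 (3.10 ± 0.80), the costimulatory receptor Tnfrsf4 (1.18 ± 0.25), Nlrp6 (1.69 ± 0.31), the glutathione transferase Gstt1 (1.63 ± 0.29) and the granzyme inhibitor Serpinb9 (0.58 ± 0.09) were higher. Itih5 (-2.10 ± 0.40) and the memory regulator Id3 (-0.90 ± 0.19) were lower. Glycolysis genes were higher in KO in 3 of 21 at LCA10 (8 adjusted over the list alone; camera adjusted p = 9.17e-08, adjusted p = 0.00885 with an estimated correlation), such as the hexokinase Hk2 (0.48 ± 0.10). At LCA50 it was 3 (12 adjusted over the list alone; camera adjusted p = 1.79e-06, adjusted p = 0.0202 with an estimated correlation), such as Gapdh (0.32 ± 0.07) and Pkm (0.21 ± 0.05). Hypoxia targets were higher at LCA10 in 2 of 22 (5 adjusted over the list alone; camera adjusted p = 1.53e-08, adjusted p = 0.0189 with an estimated correlation). They were higher in 8 at LCA50 (13 adjusted over the list alone; camera adjusted p = 8.55e-09, adjusted p = 0.0251 with an estimated correlation), with P4ha2 at 1.09 ± 0.22 and the disulfide enzyme Ero1l at 0.68 ± 0.14. NRF2 targets were higher in 2 of 24 at LCA50 (10 adjusted over the list alone; camera adjusted p = 8.32e-05, adjusted p = 0.0273 with an estimated correlation). At LCA50 370 genes were called without KO LCA50 replicate 1, 106 without WT LCA50 replicate 2 and 52 in a fit of the compared groups alone. Csf2 without KO LCA50 replicate 1 lost its call (1.41, edgeR adjusted p = 0.174). In the fit of the compared groups alone Csf2, Il9, Tnfrsf4, Itih5, Id3, Dapl1, Gapdh, Pkm, P4ha2 and Ero1l lost their calls at LCA50, at almost the same changes. Of the 10 splits of these 6 libraries, the one with the most calls (310 genes) was not that by genotype. It was afterwards seen to follow receptor background, with 121, 47.2 and 93.4 CPM on 1 side and 139, 223 and 164 on the other. It also followed the first principal component (12.1, 0.693 and 5.82 against 23.2, 29.4 and 41.9), whose group means rose with LCA dose. The 310 calls thus cannot be assigned to background rather than to the strength of the response. With the background as a covariate the genotypes differed in 278, of which 162 were among the 226.

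Several markers of myeloid cells were lower in KO. Lyz2, a lysozyme of macrophages and granulocytes (chromosome 10, 117277541 to 117282272, GRCm38), was counted in every group. It stood at 28.8 ± 5.92, 27.6 ± 5.69 and 37.6 ± 2.7 CPM in WT control, LCA10 and LCA50 and at 8.34 ± 2.54, 8.79 ± 3.36 and 10.5 ± 3.49 in KO. Its changes were -1.77 ± 0.24, -1.66 ± 0.25 and -1.85 ± 0.24. The platelet genes Itga2b (-3.52 ± 0.58) and Pf4 (25.95 ± 12.18 CPM in WT control and 2.58 ± 2.3 in KO control, not called) were low in KO control. At LCA10 Itga2b stood at 2.96 ± 2.06 CPM in WT and 3.2 ± 3.27 in KO and Pf4 at 5.24 ± 2.84 and 4.67 ± 5.54. At LCA50 Itga2b stood at 9.93 ± 2.67 CPM in WT and 2.89 ± 1.5 in KO and Pf4 at 14.34 ± 11.98 and 1.63 ± 1.67, lower in KO again. The myeloid list also holds Ccr2, chosen after its values were seen, which was not lower in KO. Ccr2 stood at 74.8 ± 13.6, 73.1 ± 1.94 and 32.8 ± 9.9 CPM in WT control, LCA10 and LCA50 and at 141 ± 9.53, 123 ± 11.1 and 68.1 ± 42.5 in KO, without a call. The neutrophil gene S100a8 had 3.31 ± 1.42 CPM in WT control and no count in the KO control libraries, and Ngp had 0.189 ± 0.327 CPM in KO control. Of the tested myeloid markers 2 of 13 fell in control cells (4 adjusted over the list alone; median -0.88; camera adjusted p = 1.1e-09, adjusted p = 0.00426 with an estimated correlation). At LCA10 1 fell (3 adjusted over the list alone; median -0.76; camera adjusted p = 1.05e-06, adjusted p = 0.0115 with an estimated correlation) and at LCA50 1 (2 adjusted over the list alone; median -0.32; camera adjusted p = 0.00429, adjusted p = 0.125 with an estimated correlation). Within WT, LCA50 lowered 3 of them (4 adjusted over the list alone; median -0.04, mean -0.70; camera adjusted p = 0.112). The red cell and platelet list had 3 tested members, of which 1 fell in KO control (3 adjusted over the list alone), and the NK and gamma delta T cell list had 3, none of them called in any comparison. Both lists were too small for camera.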

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

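The tests of explanations in this part were chosen after the results had been seen, while the difference between genotypes was planned. In the tested difference between the genotypes' responses, camera called lists although edgeR called no gene. At LCA50 the response of the effector genes (median 0.25, camera adjusted p = 0.01996, adjusted p = 0.465 with an estimated correlation), the naive and memory genes (median 0.19, camera adjusted p = 0.0195, adjusted p = 0.252 with an estimated correlation), p53 targets (median 0.21, camera adjusted p = 0.0195, adjusted p = 0.488 with an estimated correlation), glycolysis genes (median 0.08, camera adjusted p = 0.0495, adjusted p = 0.465 with an estimated correlation) and respiratory chain genes (median 0.10, camera adjusted p = 0.00102, adjusted p = 0.689 with an estimated correlation) was more positive in KO than in WT. The response of ATF4 targets was less positive in KO (median -0.07, camera adjusted p = 0.01996, adjusted p = 0.7 with an estimated correlation). At LCA10 the response of the respiratory chain genes was more negative in KO (median -0.08, camera adjusted p = 0.00988, adjusted p = 0.982 with an estimated correlation). None of these lists was called once the correlation between genes was estimated, and the difference for the respiratory chain list had opposite signs at the 2 doses.

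A signal also stood in genes that the comparisons do not use: receptor genes that T cells should not express made up 161 CPM in WT LCA50 against 79.3 CPM in WT control. The LCA50 calls may thus hold counts of library background (genomic DNA or stray reads) besides a response of the cells. If background made the calls, they should not return in KO LCA50 replicates 2 and 3, whose background was 47.2 and 93.4 CPM against 96.8, 94.0 and 113 in the KO controls. Of the WT LCA50 calls, 89.1% (891 of 1000) had the same sign there, against 61.9% of all tested genes. This argues against background as the source of the direction of most calls. It cannot show whether background enlarged their changes enough to be called. With background as a covariate, partly confounded with LCA50 in WT, 339 genes were called, 287 of them among the 1000. For calls under a mean CPM of 10 the share was 88.4% (38 of 43) for those lower but 55.1% (27 of 49) for those higher. The latter returned no more often than the 61.9% of all tested genes. Such a share does not tell background from a response. Rises of weakly expressed genes in WT LCA50 are thus not shown to be a response of the cells.

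The rise of interferon-stimulated genes at LCA10 and their fall at LCA50 may come from the dose, from another cell type, or from conditions that followed library order. Residual myeloid cells as the source should raise myeloid markers with LCA10, but their median was -0.11, which argues against a larger share of such cells. Interferon gamma from the T cells should raise guanylate-binding proteins, immunity-related GTPases and Irf1, but their median was -0.0377 against 0.64 for the other members. This does not exclude interferon gamma, since the division was chosen after its values were seen and left out Cxcl10, which interferon gamma also induces and which rose (1.52 ± 0.26), and Ifng stood at 10.4 CPM in WT LCA10 against 3.19 in WT control. A type I interferon source, or a nucleic acid sensor engaged at the lower dose, was not tested and stays open too, as does library order, which is confounded with treatment since the LCA10 libraries of both genotypes stood side by side in it.

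Lower myeloid markers in KO may reflect fewer residual myeloid cells in the KO cultures, or a loss of transcription in T cells. A naive CD8+ isolation should remove such cells, though not all of them. If fewer residual cells were the cause, the markers should be lower at every dose, and 69.2% (9 of 13) were, with Ccr2, which T cells can express too, higher in KO at each dose. That leaves both residual cells and regulation in T cells open. As the cause of all KO control calls, fewer residual cells would have to cover most of them. Marker genes or genes that followed Lyz2 across WT libraries made up 19.2% (14 of 73), under a limit of 20% set after the values were seen. Lyz2 stood at a mean of 28.8, 27.6 and 37.6 CPM in WT control, LCA10 and LCA50. Genes that followed it there may have followed dose, so the share does not measure how many calls residual cells explain. Of the 73 genes, 38 were higher in KO.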

How the results depend on the processing

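The covariate, the fit with the LCA50 library of highest background left out in each genotype, the fit without Rn45s and Lars2, the voom fit and the lists without libraries were chosen after seeing the data. So were the counts of calls shared by the genotypes under every setting but the main one. The rest were planned. Except where stated, the cause of a change was not tested. DESeq2 size factors, a mean CPM of at least 5 and leaving out Rn45s and Lars2 kept every count within 1.5 times. DESeq2 gave 70 calls in WT LCA10, 62 in KO LCA10 and 1 in the LCA50 response difference. Without a filter there were 104 in WT LCA10, 103 in KO LCA10, 141, 142 and 357 in KO against WT at control, LCA10 and LCA50, and 3 and 3 in the response differences at LCA50 and LCA10. glmTreat, a stricter test by construction, called 44 in WT LCA50, 1 in WT LCA10, 39 in KO LCA50, 2 in KO LCA10, 13, 9 and 15 between genotypes at control, LCA10 and LCA50, 113 and 12 in averaged LCA50 and LCA10, 7 between doses and 19 shared by the genotypes. Only the groups compared gave 136 in WT LCA10, 372 in KO LCA50, 123 in KO LCA10, 211, 128 and 52 between genotypes, 1 in the LCA10 response difference, 380 in averaged LCA10 and 261 shared.

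The background covariate, partly confounded with LCA50 in WT, gave 339 calls in WT LCA50, 79 in WT LCA10, 123 between genotypes at LCA10, 5 in the LCA50 response difference, 283 between doses and 190 shared. In KO LCA50 it gave 998 calls, 738 of them among the 740 of the main fit. With both LCA50 libraries left out there were 113 in WT LCA10, 428 in KO LCA50, 98 in KO LCA10, 152 and 158 between genotypes at control and LCA10, 350 in averaged LCA10, 383 between doses and 280 shared, while WT LCA50 had 883 (750 of them among the 1000) and KO against WT at LCA50 214 (131 of them among the 226). ATF4 targets up were then 33 in WT and 19 in KO, and interferon-stimulated genes numbered 23 up in averaged LCA10 and 33 down between doses. limma-voom gave 113 in WT LCA10, 125 in KO LCA10, 167 and 141 between genotypes at control and LCA10, and 361 in averaged LCA10. With the replicate block WT LCA50 had 930, KO LCA50 684 and the dose comparison 638 calls, all contrasts within 1.5 times. The block was left out of the main fit beforehand, since the labels do not say what the replicate number marks. Libraries paired by number were not alike either (median r -0.00125 over 45 pairs, 0 over 0.1).

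With each library left out in turn, calls ran from 522 to 1027 in WT LCA50 (lowest without WT LCA50 replicate 3, 533 without replicate 2, 664 without WT control replicate 3), 4 to 57 in WT LCA10 (WT LCA10 replicate 2; 28 without replicate 1, 24, 20 and 23 without WT control replicates 1, 2 and 3), 384 to 814 in KO LCA50 (KO control replicate 3; 475 and 428 without replicates 1 and 2, 435 without KO LCA50 replicate 1) and 6 to 45 in KO LCA10 (KO LCA10 replicate 2; 17 and 10 without KO control replicates 2 and 3). KO against WT ran from 28 to 53 in control (KO control replicate 2; 34 and 39 without replicates 1 and 3, 32 and 35 without WT control replicates 1 and 3), 43 to 62 at LCA10 (KO LCA10 replicate 1; 48 without replicate 3, 49, 45 and 45 without WT LCA10 replicates 1, 2 and 3) and 106 to 370 at LCA50 (WT LCA50 replicate 2 and KO LCA50 replicate 1; 122 without WT LCA50 replicate 3). Response differences gave 0 to 6 at LCA50 (highest without KO LCA50 replicate 1, 1 without replicate 3) and 0 to 0 at LCA10. Averaged LCA50 ran from 1504 to 1983, averaged LCA10 from 106 to 201 (WT LCA10 replicate 2; 130 without WT control replicate 2, 136 and 116 without KO control replicates 1 and 3, 115 without KO LCA10 replicate 2), the doses from 409 to 819 (WT LCA50 replicate 2; 444 without replicate 3, 437 without WT LCA10 replicate 3), shared calls from 284 to 433 (KO control replicate 3) and Nr4a1 in KO against WT control from -0.11 to 0.32.

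Of 542 called values of named genes, none turned direction, and 88 kept their call under all settings, glmTreat included, and 324 without each library in turn. Cth in WT LCA50 lost its call without WT control replicates 1 and 2 and WT LCA50 replicate 2 (adjusted p = 0.0632, 0.0637 and 0.0594). Ifng in KO LCA50 lost it without KO control replicate 3 (0.118). Of 312 gene list tests, 129 were called, 40 with an estimated correlation, 83 with fry and 124 with the block. Lists whose direction turned, with their range over libraries left out, were the respiratory chain in KO LCA10 (adjusted p = 0.663 without KO LCA10 replicate 3, range 0.000316 to 0.663), the interferon list in the LCA10 response difference (0.0185 without WT LCA10 replicate 2, 0.0185 to 0.978), and, without KO LCA50 replicate 1, ATF4 targets (0.0188, 0.000423 to 0.985), cholesterol synthesis (0.0402, 6.73e-07 to 0.548) and CD8 markers (0.0402, 0.0402 to 0.703) in KO against WT at LCA50 and cholesterol synthesis in the LCA50 response difference (6.89e-05, 6.89e-05 to 0.779). With both LCA50 libraries left out these were 0.0447 for ATF4 targets, 0.121 for cholesterol synthesis and 0.000465 for its response difference. At 4113713 to 5945518 counts a library, 11651 of 24537 symbols could be tested, and weakly expressed cytokines rest on few counts.

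Other splits of the libraries were too few to judge the 3 against 3 contrasts, with 10 each. The real grouping alone (1 split) reached its count in WT LCA50 (1000), WT LCA10 (45), KO LCA50 (740), KO LCA10 (38) and KO against WT in control (73) and LCA10 (77), where the highest other split called 0. In KO against WT at LCA50 2 splits did, since WT LCA50 replicate 1 with KO LCA50 replicates 2 and 3 against the rest called 310, which points to structure other than genotype. This split follows receptor background, with 121, 47.2 and 93.4 against 139, 223 and 164 CPM. It also follows the first principal component, with 12.1, 0.693 and 5.82 against 23.2, 29.4 and 41.9. Background and the strength of the response to LCA cannot be told apart in it. With background as a covariate the genotypes differed in 278 genes, 162 of them among the 226 of the main fit. Over 100 splits within genotype, the real grouping was the highest (1 split) for averaged LCA50 (1925 against 437 in the highest other), averaged LCA10 (212 against 15), the doses (667 against 198) and shared calls (429 against 0), and for medians of ATF4 targets (0.51 against 0.42) and interferon-stimulated genes at LCA10 (0.46 against 0.40) and between doses (-0.89 against 0.64). For the response differences the real count was 0, which all 100 splits reach whatever the data, so they cannot judge it. The highest other splits called 434 and 302 genes, and both were the split that swaps KO and WT in the treated groups alone, so they measure the difference between genotypes itself. Both doses were set against the same controls, so their changes correlate by construction: simulated r was 0.497 in WT and 0.485 in KO against 0.517 and 0.525 observed, with covariances of 0.0422 and 0.039 against 0.0789 and 0.0715.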

Other observations

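These values were picked after seeing the results, and no explanation of them was tested. Ifng was low in control and stood higher with each dose in both genotypes, at 3.19 ± 0.765, 10.4 ± 7.78 and 13.8 ± 1.93 CPM in WT and 1.41 ± 1.77, 6.14 ± 1.14 and 11.7 ± 8.17 in KO for control, LCA10 and LCA50. The cytokine genes Csf2 and Il9 stood highest in KO LCA50, Csf2 at 9.43 ± 8.22 against 1.77 ± 0.617 CPM in WT LCA50. Lmna, a structural gene that also follows T cell activation, was among the largest rises at both doses, from 21.6 ± 5.22 through 64.6 ± 18.8 to 117 ± 7.07 CPM in WT and from 38.2 ± 7.86 through 111 ± 26.5 to 181 ± 29.1 in KO. Hic1 fell at both doses, from 18.72 ± 7.06 to 4.38 ± 0.66 and 3.10 ± 0.79 CPM in WT and from 14.98 ± 4.69 to 2.39 ± 1.01 and 2.10 ± 1.09 in KO. Genes called at both doses in the same direction numbered 31 in WT and 28 in KO. The doses share their control libraries, and simulated data without any change but with shared controls gave at most 1 in WT and 0 in KO over 20 simulations. Since no gene was changed at either dose there, few could be called at all. The simulation thus cannot show how many shared calls the controls add when LCA50 changes many genes.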
